A study of Mus musculus with 8 samples.

How the data were processed

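Chromatin accessibility was measured by ATAC-seq in 8 libraries of type 1 conventional dendritic cells sorted from mouse tumours, 4 at day 7 and 4 at day 21. The authors deposited raw counts per genomic region, with 1 column per library over 1 shared set of 128057 regions. The counts are whole numbers and are not normalized. Per the submitters' processing notes, cutadapt 1.9, Picard 1.65, SAMtools, MACS2 2.1.0.20150603 and bedtools were used with the builds mm10 and GRCm38. The aligner is not given in the sources used here. The read filters, the rule that merged peaks into shared regions, and whether reads, fragments or transposase insertions were counted are also not given in the sources used here, and neither is whether positions were shifted for the transposase. A shift of insertion positions changes where a count falls by a few bases. Regions had a median width of 364 bp (range 1 to 3427), and the effect of a shift was not tested. Every column belonged to 1 of the 8 libraries.

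Groups and replicate numbers came from the sample labels. Total counts in regions ran from 9440223 to 16063736 at day 7 and from 14021151 to 27737040 at day 21.

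Genes came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10. The table gives the chromosome, start and end of a gene but no strand, exons or untranslated regions. The design fixed before the data were examined used windows of 1000 bp on each side of transcription start sites. Because the table does not say which end of a gene is its start, windows of 1000 bp on each side of both annotated ends were used in their place, and the term gene ends refers to these windows. A gene's value was the sum of the counts of all regions overlapping its windows. Of 21887 protein-coding genes, 13723 had a region at an end, 10697 of them (77.9%) at 1 end and 3026 at both. A region that overlapped the windows of several genes counted for each, which affected 3872 genes (28.2%). Distal values summed the regions outside all gene-end windows whose centre had that gene's end as its nearest protein-coding gene end, within 50 kb. Regions were classed as gene end (17960), gene body (60390), intergenic (49649) or on an unplaced contig (58). Coordinates are those of the deposited table, whose counting base (0 or 1) is not given in the sources used here.

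Counts were tested with edgeR 4.0.16 in R 4.3.3. Regions were filtered with filterByExpr, which left 121865 regions, and libraries were scaled with TMM factors (0.978 to 1.01). A quasi-likelihood model with the day as its only term was fitted with glmQLFit on a trended dispersion and tested with glmQLFTest. The gene-end sums (13572 genes) and distal sums (14484 genes) were tested in the same way with the factors of the region fit. Adjusted p values are Benjamini-Hochberg values and 0.05 was the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.133 (0.138 at day 7 and 0.132 at day 21). CPM values come from edgeR's cpm function on TMM-scaled totals and are given as mean ± SD over the 4 libraries of a day.

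24 gene lists were fixed before the data were examined: 17 for functions of dendritic cells and metabolism, and 7 for markers of other cell types that the sort could hold. Of their 694 genes, 690 were found in the gene table; Mx1, Mx2, Cxcl11 and Lilrb4b were not. The T and NK cell, B cell, macrophage, neutrophil, pDC, melanoma and stromal lists share no gene with another list, whereas 10 of the 30 dendritic cell maturation genes stand in another list. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. An estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. Fry does not compare a list with other genes, so a fall shared by most gene ends can pass it. Values of libraries were compared with exact two-sided permutation tests over the 70 relabelings (SciPy 1.17.1), whose smallest possible p is 0.0286. Medians of lists were also placed among 10000 random lists of gene ends matched in 20 bins of mean log2 CPM.

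The genes and regions named were chosen by a rule fixed before the data were examined. It took the 10 higher and 10 lower regions with the smallest p among those past the threshold with at least a 2-fold change and no overlap between the libraries of the days, 1 region per gene. It added 22 genes fixed by name, all of which were measured at their ends, and for each list the 2 genes with the smallest p at gene ends and the 2 in distal regions. Some genes and regions that this rule chose are not reported here, while all counts and list tests include them. Other list members named as examples were chosen after their values were seen.

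Each procedure was tested on simulated data in which 200 features were changed by known folds. Of 1.5-fold, 2-fold and 4-fold changes, 17.9%, 52.2% and 95.5% were recovered in the simulation of 121865 regions, 77.6%, 95.5% and 100% in that of 13572 gene-end sums, and 76.1%, 85.1% and 100% in that of 14484 distal sums. A list shifted by 1.3-fold was called by camera, and 0 of the other simulated lists were. Features were simulated independently, so this could not show false calls that come from correlation between genes.

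Alternatives fixed before the data were examined were RLE size factors, library totals alone, trended offsets (which remove each library's average trend with abundance), DESeq2 1.42.0, limma-voom, 2 other low-count filters (none, or 10 counts in 4 libraries), the replicate number as a block, glmTreat against a 1.5-fold change, windows of 500 and 2000 bp, distances of 20 and 100 kb, and leaving out each library in turn. Trended offsets were fitted on regions, gene-end sums and distal sums separately, so they also remove the average shift of each set. Ranges of adjusted p over alternatives leave out glmTreat, which tests another null hypothesis. Thinning every library to the smallest total and using only the gene end with more counts were added after seeing the data. Motif enrichment, motif accessibility and corrections for GC content need the genome sequence, which was not used here, and these tests were not run. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.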

Results

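Accessible chromatin was profiled in conventional type 1 dendritic cells (cDC1s), the dendritic cell subset specialised in presenting captured antigen to CD8 T cells. The cells were sorted from B16-OVA tumours, a mouse melanoma line that carries ovalbumin as a model antigen, in wild-type mice. In ATAC-seq a transposase inserts sequencing adapters into open DNA, so the count of a region measures how accessible it is. 4 libraries came from tumours at day 7 after inoculation and 4 from tumours at day 21. Total counts in regions were 11884889, 9440223, 11966868 and 16063736 in the day 7 libraries (replicates 1 to 4). They were 14021151, 16761537, 17345638 and 27737040 in the day 21 libraries. The labels do not say whether the libraries of a day came from separate animals, so p values measure the spread between these libraries. Coordinates are on mm10. Gene and region p values are from edgeR's quasi-likelihood test and list p values from camera, with n = 4 per day throughout.

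The comparison asks how the chromatin of cDC1s in an early tumour differs from that in a late tumour, within a study of mitochondrial metabolism and signalling in dendritic cells. By day 21 accessibility had dropped at 16 of 29 genes of dendritic cell maturation and migration at their ends and at 15 of 28 in distal regions, while 12 and 10 did not pass; with an estimated correlation the lists had adjusted p = 0.517 and 0.270, and distal T and NK cell markers fell too, at 8 of 21. At the ends of Ccr7, the receptor that guides mature dendritic cells to lymph nodes, it fell from 32.4 ± 2.34 to 12.7 ± 3.21 CPM (log2 fold change −1.36 ± 0.10, edgeR adjusted p = 3.10e-17). Accessibility rose at Cd74, the invariant chain of MHC class II, from 217 ± 7.55 to 427 ± 39.0 CPM at its gene ends (0.98 ± 0.05, edgeR adjusted p = 1.77e-26), and at Fos, a subunit of the AP-1 transcription factor, from 105 ± 7.90 to 200 ± 14.2 CPM (0.93 ± 0.06, edgeR adjusted p = 4.64e-23). The Cd74 gain was uneven. A region at 1 end, shared with Tcof1, rose by 1.75 ± 0.06, while regions at the other end changed by 0.22 ± 0.05 and −0.84 ± 0.11. Most of the Fos gain lay in 1 region at an end of Fos, which rose from 37.2 ± 5.88 to 122 ± 12.3 CPM. Gene ends of the mitochondrial respiratory chain and the mitochondrial ribosome were lower by small amounts at 31 and 30 of 74, while 43 and 42 did not pass. The list medians were −0.18 and −0.19 on the log2 scale, against −0.09 over all gene ends. With trended offsets they were −0.08 and −0.10, against −0.004 over all gene ends. Camera with an estimated correlation gave both lists an adjusted p of 0.517.

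Of 121865 regions tested, 11573 were higher and 12017 lower at day 21, among them 1945 higher and 4579 lower by at least 2-fold. In 19.8% of all tested regions the libraries of the days did not overlap, against 2.86% by chance. The gain with the smallest p lay between genes, 2.27 kb from Atf3, a stress-induced transcription factor of the AP-1 family (chromosome 1, 191167091 to 191168957). It rose from 10.6 ± 2.23 to 95.3 ± 17.6 CPM (3.14 ± 0.10, edgeR adjusted p = 1.37e-36). A region on the other side of it (chromosome 1, 191169654 to 191170264) rose by 3.15 ± 0.13. A neighbouring region (chromosome 1, 191165573 to 191166079), assigned to Fam71a by distance, rose by 2.96 ± 0.16. The region over the end of Cd74 (chromosome 18, 60811156 to 60814308), which also overlaps Tcof1 and Mir5107, rose from 85.9 ± 5.85 to 288 ± 38.7 CPM (1.75 ± 0.06). Nearby, a region in the body of Tcof1 (chromosome 18, 60819551 to 60819941) rose by 2.56 ± 0.13. Gains also lay at an end of Fos (chromosome 12, 85477249 to 85479120, 1.70 ± 0.07), of Fosb (chromosome 7, 19301182 to 19303354, 1.95 ± 0.09), of the antiproliferative gene Btg2 (chromosome 1, 134073843 to 134075060, 1.92 ± 0.10). An end of Dnajb13 (chromosome 7, 100502306 to 100504440) rose by 1.80 ± 0.09. A region near Hspa5, which encodes a chaperone of the endoplasmic reticulum, lay in the body of Rabepk (chromosome 2, 34777663 to 34778866) and rose by 2.53 ± 0.14.

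Among the losses with the smallest p was a region between genes 10.0 kb from Ccr7 (chromosome 11, 99164841 to 99165361), which fell from 17.8 ± 2.68 to 4.92 ± 1.06 CPM (−1.85 ± 0.14, edgeR adjusted p = 1.99e-16). The end of Cxcr5, the receptor for the chemokine of B cell follicles (chromosome 9, 44526402 to 44527073), fell from 12.3 ± 1.66 to 1.96 ± 0.561 CPM (−2.65 ± 0.18). Slco5a1, a member of the organic anion transporter family, lost accessibility at a gene end (chromosome 1, 12991540 to 12992900, −1.72 ± 0.13). The largest fold among these losses was in the body of Inpp5b (chromosome 4, 124795198 to 124795727), from 10.6 ± 1.39 to 1.10 ± 0.861 CPM. Further losses lay 7.94 kb from Tmem19 (chromosome 10, 115332182 to 115333408, −1.88 ± 0.13) and 3.17 kb from Swap70 (chromosome 7, 110286178 to 110287178, −1.86 ± 0.14). The others were in the bodies of Tbc1d8 (chromosome 1, 39430647 to 39431274, −2.03 ± 0.14), Nsmce1 (chromosome 7, 125481895 to 125482700, −2.48 ± 0.17) and Pcgf5 (chromosome 19, 36374971 to 36375901, −1.17 ± 0.09). The adjusted p of the regions named lay between 1.37e-36 and 1.99e-16.

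**Figure D1:**
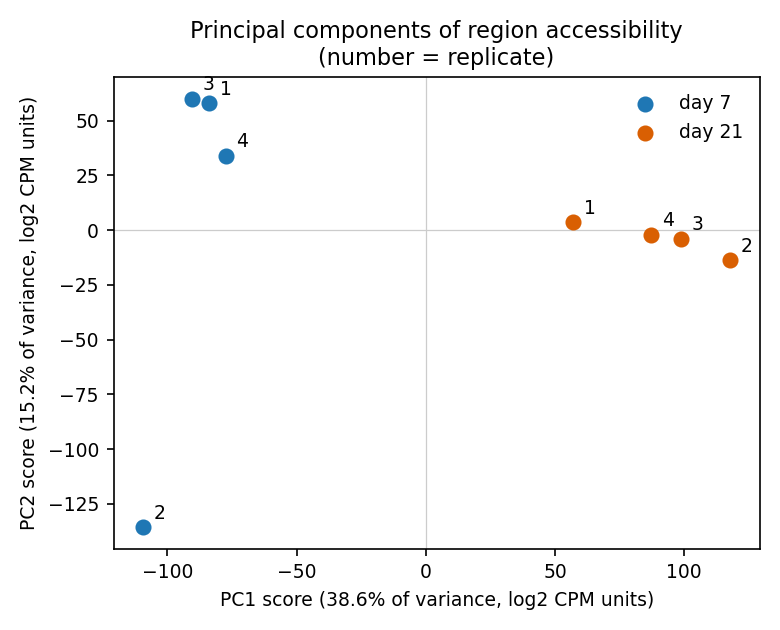
Scores of the 8 libraries on the first and second principal components of log2 CPM over tested regions, with day 7 in blue and day 21 in orange. Day 7 libraries lie between −109 and −77.4 and day 21 libraries between 57.1 and 118 on the first component (38.6% of variance), and day 7 replicate 2 stands apart at −136 on the second (15.2%).

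Direction differed between classes of regions. Of 17636 tested regions at gene ends, 1170 were higher and 2928 lower. Gene bodies had 6138 higher and 4623 lower of 57384, and regions between genes 4261 higher and 4434 lower of 46788. On unplaced contigs 4 of 57 tested regions were higher and 32 lower. Among changed regions, gains were rarer at gene ends than elsewhere (odds ratio 0.348, Fisher's exact p = 6.11e-190, in which regions are not independent replicates). With trended offsets 1159 regions at gene ends were higher and 3121 lower (Fisher's exact p = 1.54e-187). Summed per gene, 911 of 13572 genes were higher and 3339 lower at their ends, and 2654 of 14484 were higher and 1654 lower in distal regions. With trended offsets the sums per gene split into 1628 higher and 1647 lower at gene ends and 2164 higher and 2167 lower in distal regions. For these sums the offsets were fitted on the sums themselves and so remove their average shift. For regions they were fitted over all classes together. The even split of the sums is therefore built in and does not test the excess of losses at gene ends. The share of a library's counts at gene ends was 38.6% ± 0.602 at day 7 and 36.4% ± 0.286 at day 21, without overlap. The exact permutation p was 0.0286, the smallest that 4 against 4 can give, and 0.0571 after adjustment over 10 library measures. A shift between gene ends and other regions can be a change in the cells or a sign of library quality, and these were not told apart.

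Dendritic cell maturation and migration genes formed a list of 29 measured at their ends, of which 16 fell, 1 rose and 12 did not pass (camera adjusted p = 0.0106, median −0.19). With an estimated correlation the adjusted p was 0.517, the highest of 17 alternatives whose lowest was 4.20e-04. Adjusted over the list alone, 17 fell and 1 rose. With trended offsets 14 fell and 4 rose. Besides Ccr7, accessibility fell at Slco5a1 (−1.24 ± 0.10, edgeR adjusted p = 6.82e-16), at Fscn1, the actin-bundling protein fascin (−1.76 ± 0.17), and at Ccl5, a chemokine that attracts T cells (−1.74 ± 0.17). The exception was Cacnb3, a calcium channel subunit, which rose at its ends (0.96 ± 0.37, edgeR adjusted p = 0.0425) and fell in distal regions (−0.29 ± 0.06). This gain did not hold: windows of 2000 bp reversed it (−1.37, adjusted p = 6.91e-10), and it was lost without 6 of the 8 libraries (up to 0.117, without day 7 replicate 4), after thinning (0.130), with limma-voom and with the replicate number as a block. Its adjusted p ran from 6.91e-10 to 0.130 over 20 alternatives. In distal regions 15 of 28 genes fell, 3 rose (Ccl17, Cd83 and Birc3) and 10 did not pass (camera adjusted p = 1.99e-05, median −0.19). The estimated correlation gave 0.270 there, the highest of 16 alternatives whose lowest was 6.64e-06. Cd83 lost its call with trended offsets (0.382, the highest of 19 alternatives whose lowest was 8.34e-04). Birc3 lost its call without 4 libraries (up to 0.0787, without day 21 replicate 4), in a range of 0.00525 to 0.106 over 19 alternatives. Adjusted over the list alone 15 fell and 4 rose, and with trended offsets 17 fell and 1 rose. Distal Ccr7 regions fell from 107 ± 8.50 to 57.3 ± 6.96 CPM (−0.90 ± 0.06, edgeR adjusted p = 1.49e-18) and distal Slco5a1 regions by 0.80 ± 0.08 on the log2 scale. Markers of T and NK cells moved with this group: in distal regions 8 of 21 fell, 1 (Cd4) rose and 12 did not pass (camera adjusted p = 0.0233, median −0.25). Their adjusted p was 0.270 with an estimated correlation, the highest of 16 alternatives whose lowest was 0.00283, and the counts adjusted over the list alone were the same. Cd4 lost its call without 6 libraries (up to 0.139, without day 21 replicate 2), in a range of 0.00862 to 0.139 over 19 alternatives.

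**Figure D2:**
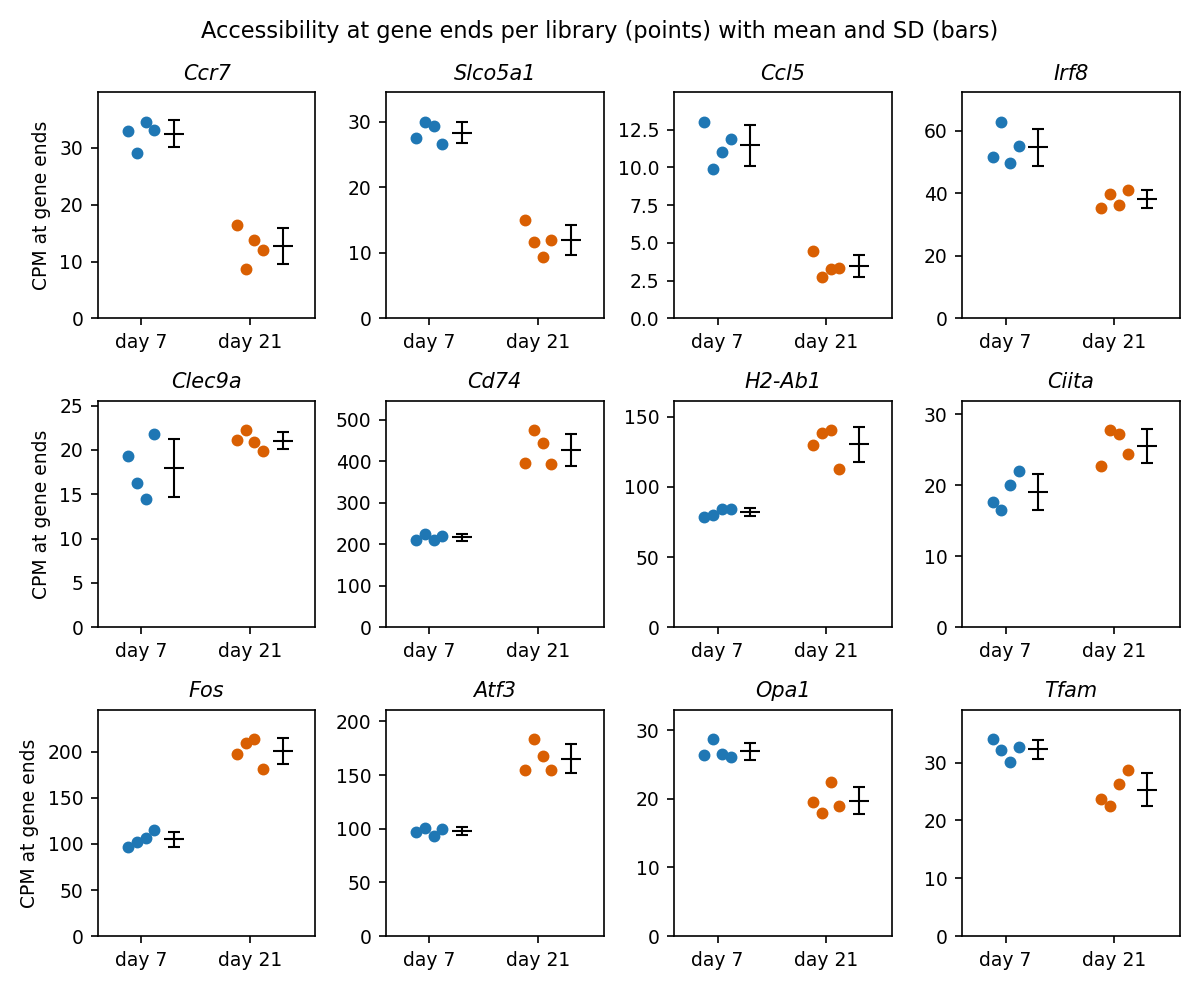
CPM at gene ends in each library (points) at day 7 (blue) and day 21 (orange) for 12 genes, with bars for the mean and SD of 4 libraries and every axis starting at 0. Ccr7, Slco5a1 and Ccl5 are lower at day 21 in every library, Cd74, H2-Ab1, Fos and Atf3 are higher in every library, and Clec9a overlaps between the days.

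MHC class II presentation genes gained accessibility at 8 of 16 gene ends and lost it at 5, and 3 did not pass (camera adjusted p = 0.00235, median 0.20). The adjusted p was 0.517 with an estimated correlation, the highest of 17 alternatives whose lowest was 4.20e-04. Adjusted over the list alone 9 rose and 5 fell, and with trended offsets 10 rose and 3 fell. The Cd74 region shared with Tcof1, at 1 end of Cd74, rose by 1.75 ± 0.06, while regions at the other end changed by 0.22 ± 0.05 and −0.84 ± 0.11. Besides Cd74, H2-Ab1 rose from 81.9 ± 2.76 to 130 ± 12.3 CPM (0.67 ± 0.06, edgeR adjusted p = 6.64e-15). Taking only the H2-Ab1 end with more counts, the change was 0.12 (adjusted p = 0.135, the highest of 20 alternatives whose lowest was 1.05e-20), so the gain lay at the other end. Ciita, the master regulator of MHC class II transcription, rose from 19.0 ± 2.51 to 25.5 ± 2.37 CPM (0.41 ± 0.09, edgeR adjusted p = 6.60e-04). The genes that fell were Ifi30 (−0.36 ± 0.08) and Lgmn (−0.32 ± 0.07), enzymes that process antigen in lysosomes, and H2-DMa (−0.23 ± 0.07), which helps load peptide. Rfxank (−0.24 ± 0.06) and Rfxap (−0.25 ± 0.08), subunits of the factor that binds class II promoters, also fell. H2-DMa lost its call with trended offsets and with windows of 2000 bp (0.159, the highest of 20 alternatives whose lowest was 8.11e-05). Rfxap lost its call without day 21 replicate 4 (0.0591), in a range of 0.00618 to 0.161 over 20 alternatives. In distal regions 14 of 17 genes rose, 0 fell at an adjusted p under 0.05 and 3 did not pass (camera adjusted p = 4.84e-05, median 0.24). Here the estimated correlation gave 0.270, the highest of 16 alternatives whose lowest was 2.32e-05. Adjusted over the list alone 15 rose and 0 fell, and edgeR gave 15 of 17 an unadjusted p under 0.05. H2-Ab1 rose there from 131 ± 4.67 to 188 ± 14.5 CPM (0.52 ± 0.05) and H2-Eb1 from 53.8 ± 3.39 to 81.9 ± 3.48 CPM (0.60 ± 0.06). Among macrophage and monocyte markers, cells that also carry MHC class II, 5 of 21 rose at gene ends, 1 fell and 15 did not pass (camera adjusted p = 0.0695). C1qc, a complement subunit made by macrophages, rose from 3.53 ± 0.388 to 7.63 ± 1.61 CPM (1.11 ± 0.19, edgeR adjusted p = 5.12e-06).

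MHC class I presentation genes did not pass in camera, which compares a list with the other genes. At gene ends 7 of 22 fell and 15 did not pass (7 adjusted over the list alone; camera adjusted p = 0.216), with 5 lower and 2 higher under trended offsets. With fry, which tests the list by itself, the adjusted p was 0.00667, the lowest of 17 alternatives whose highest was 0.664. The list's median lay at percentile 67.2 of matched random lists of gene ends. In distal regions 3 of 17 rose, 3 fell and 11 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.882, test downward with a median of 0.06 and a mean of 0.03). B2m, the light chain of class I molecules, fell from 73.4 ± 6.74 to 57.1 ± 1.67 CPM at its ends (−0.36 ± 0.06, edgeR adjusted p = 8.06e-06) and by 0.46 ± 0.08 in distal regions. Nlrc5, the transcriptional activator of class I genes, fell by 0.37 ± 0.09 (edgeR adjusted p = 9.08e-04) and Irf1 by 0.27 ± 0.06. H2-K1 had 60.2 ± 2.93 and 58.0 ± 2.80 CPM (−0.05 ± 0.06, edgeR adjusted p = 0.583). The peptide transporter gene Tap1, whose ends share regions with Psmb8 and Psmb9, had 0.07 ± 0.06 (edgeR adjusted p = 0.359). Over 20 alternatives its adjusted p ran from 0.00753, with trended offsets, to 0.768.

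Oxidative phosphorylation genes fell at 31 of 74 gene ends, 0 rose and 43 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.00893, median −0.18). This adjusted p rose to 0.517 with an estimated correlation, the highest of 17 alternatives whose lowest was 0.00326. With trended offsets 18 fell and 4 rose, and the median was −0.08. Ndufs7, a subunit of complex I, fell from 28.0 ± 0.871 to 18.7 ± 1.51 CPM (−0.57 ± 0.09, edgeR adjusted p = 1.13e-06). Ndufb4 fell by 0.47 ± 0.08 and Cycs, which encodes cytochrome c, by 0.28 ± 0.06 (edgeR adjusted p = 6.38e-04). Ndufs1, whose ends share a region with Eef1b2, fell by 0.29 ± 0.09 (edgeR adjusted p = 0.00657). This call was lost without day 21 replicate 4 (0.0872) and with trended offsets (0.0964, the highest of 20 alternatives whose lowest was 0.00133). Mitochondrial ribosome genes fell at 30 of 74 gene ends, 2 rose (Mrps25 and Mrpl42) and 42 did not pass (camera adjusted p = 0.0173, median −0.19). An estimated correlation gave 0.517 here too, the highest of 17 alternatives whose lowest was 0.00365. Mrpl42 lost its call without 3 libraries (up to 0.124, without day 21 replicate 4), in a range of 4.08e-04 to 0.722 over 20 alternatives. Adjusted over the list alone 31 fell and 2 rose, and with trended offsets 14 fell and 3 rose. Mrps18b, which shares regions with Atat1 and Ppp1r10, fell by 0.31 ± 0.06 and Mrpl17 by 0.28 ± 0.06.

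In distal regions 7 of 40 oxidative phosphorylation genes fell, 4 rose and 29 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.120, median −0.09). With fry the adjusted p was 0.00504, the lowest of 16 alternatives whose highest was 0.270. Distal regions of Ndufs1 fell by 1.05 ± 0.15, and those of Atp5pb, a subunit of ATP synthase, from 3.20 ± 0.0301 to 0.769 ± 0.344 CPM. For the mitochondrial ribosome 9 of 49 rose, 3 fell and 37 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.960; 7 and 4 with trended offsets). Distal Mrpl13 rose by 0.32 ± 0.07 and distal Mrpl45 fell by 0.54 ± 0.12. Genes of mitochondrial dynamics, biogenesis and mitophagy went both ways. At gene ends 3 of 36 rose, 9 fell and 24 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.808). With trended offsets 7 rose and 4 fell, and the median moved from −0.08 to 0.00. With fry the adjusted p was 0.0487, the lowest of 17 alternatives whose highest was 0.985. Among matched random lists of gene ends the median lay at percentile 73.2. Mfn2, a mitochondrial fusion protein, fell from 26.5 ± 2.42 to 15.5 ± 1.62 CPM (−0.77 ± 0.10, edgeR adjusted p = 4.15e-09). Opa1, which fuses the inner membrane, fell from 26.9 ± 1.20 to 19.7 ± 1.98 CPM (−0.45 ± 0.09, edgeR adjusted p = 1.11e-04) and Tfam, which binds mitochondrial DNA and drives its transcription, from 32.3 ± 1.61 to 25.3 ± 2.83 CPM (−0.34 ± 0.08, edgeR adjusted p = 0.00111). Polg2 rose by 0.58 ± 0.06 at ends that share a region with Ddx5, and Ppargc1a (0.32 ± 0.09) and Ppargc1b (0.33 ± 0.08), coactivators of mitochondrial biogenesis, also rose. The Ppargc1b call was lost with windows of 500 bp (0.541, the highest of 20 alternatives whose lowest was 3.01e-05). Nrf1, a transcription factor of nuclear genes for mitochondrial proteins, had −0.15 ± 0.08 (edgeR adjusted p = 0.132), and without day 7 replicate 4 its adjusted p was 0.0422 (0.0422 to 0.742 over 20 alternatives). Tfeb, a regulator of lysosome genes, had −0.03 ± 0.06 (edgeR adjusted p = 0.775). In distal regions 7 of 31 rose, 3 fell and 21 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.918; 5 and 4 with trended offsets). Distal Chchd3 rose by 0.77 ± 0.07 and the outer membrane channel gene Vdac1 fell by 0.69 ± 0.09.

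**Figure D3:**
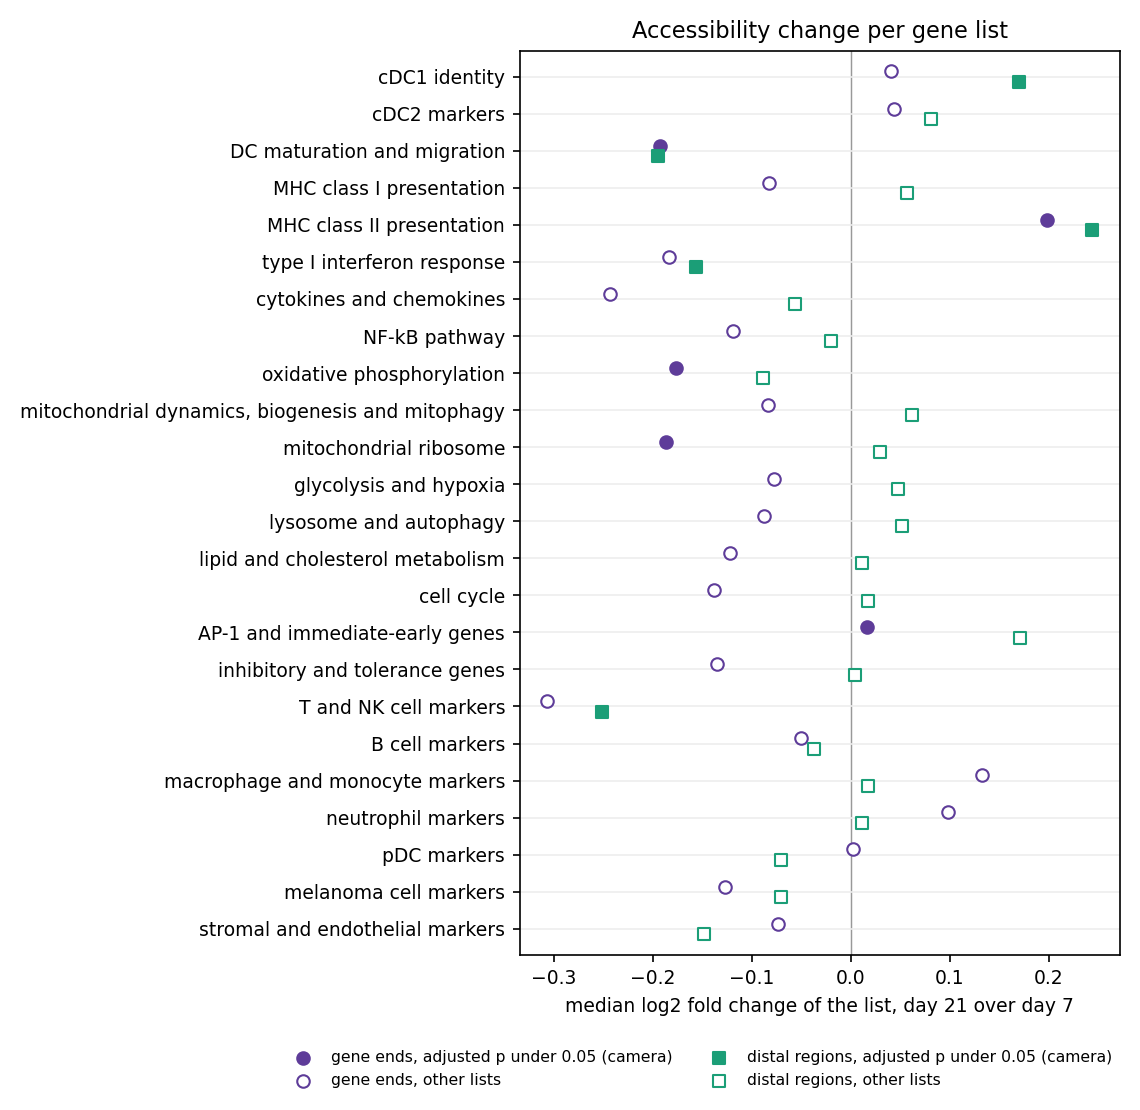
Median log2 fold change (day 21 over day 7) of each of the 24 gene lists at gene ends (purple circles) and in distal regions (green squares), filled where the camera adjusted p was under 0.05. MHC class II presentation lies at 0.20 and 0.24 and dendritic cell maturation at −0.19 on both; with an estimated correlation 0 lists had an adjusted p under 0.05.

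AP-1 and immediate-early genes, which respond within minutes to stimulation, split in direction. At gene ends 9 of 27 rose, 8 fell and 10 did not pass (camera adjusted p = 0.0246, upward, with a median of 0.02 and a mean of 0.09). Its adjusted p was 0.664 with an estimated correlation, the highest of 17 alternatives whose lowest was 0.0108. Adjusted over the list alone 9 rose and 9 fell, and with trended offsets 12 rose and 6 fell. Fos and Atf3 (97.7 ± 3.55 to 165 ± 13.6 CPM, 0.76 ± 0.06, edgeR adjusted p = 2.23e-18) rose, as did Fosb by 0.88 ± 0.07 and Jun by 0.55 ± 0.06. The Fos gain lay mostly in 1 region at an end, which rose by 1.70 ± 0.07. Regions at 1 end of Atf3 rose by 3.15 ± 0.13 and 3.13 ± 0.17. Those at its other end had 0.35 ± 0.06 and 0.09 ± 0.12, the last not past the threshold. The genes that fell included the nuclear receptors Nr4a2 (−0.29 ± 0.07) and Nr4a3 (−0.26 ± 0.06) and the zinc finger genes Egr3 (−0.28 ± 0.07) and Egr1 (−0.14 ± 0.06). Egr1 lost its call without 6 libraries (up to 0.153, without day 7 replicate 3), in a range of 0.0171 to 0.415 over 20 alternatives. The list's call was lost without day 21 replicate 3 (adjusted p = 0.102, median −0.02) and with only the end with more counts (0.227, median −0.06). It was also lost with fry (0.164). In distal regions 14 of 27 rose, 6 fell and 7 did not pass (16 and 6 adjusted over the list alone; camera adjusted p = 0.106), or 10 and 7 with trended offsets. There fry gave 0.0456, the lowest of 16 alternatives whose highest was 0.902. Distal regions of Klf2, a Krüppel-like transcription factor, rose from 37.8 ± 4.32 to 79.3 ± 13.9 CPM (1.06 ± 0.08) and those of Atf3 by 0.68 ± 0.05.

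**Figure D4:**
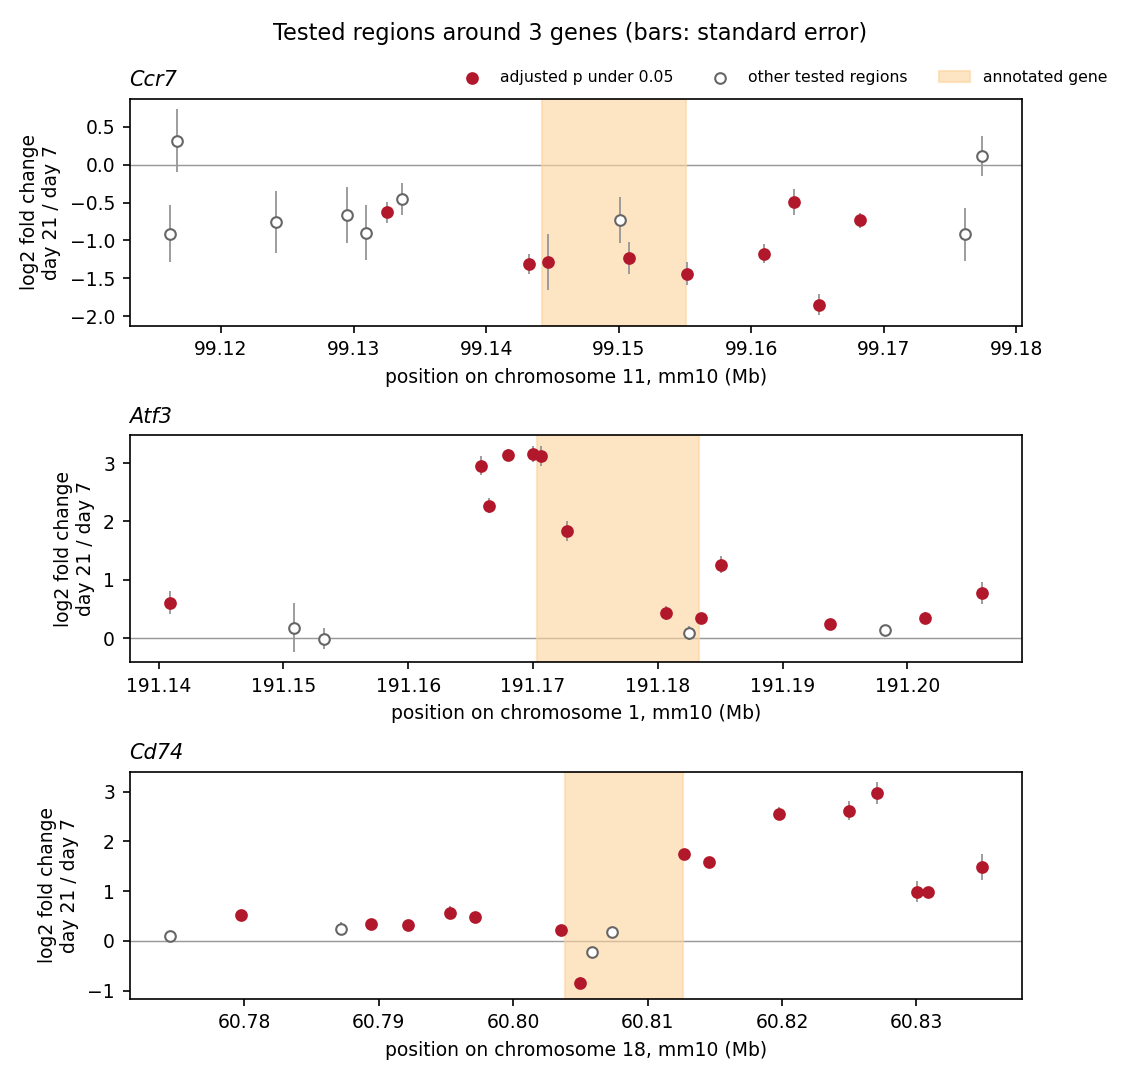
Log2 fold change (day 21 over day 7, with standard error) of every tested region within 30 kb of Ccr7, Atf3 and Cd74 against its position on mm10, with red points at an adjusted p under 0.05, open points for other regions and the annotated gene shaded. Around Ccr7 9 of 18 regions were lower and 0 higher, around Atf3 13 of 17 were higher and 0 lower, and around Cd74 14 of 19 were higher and 1 lower.

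Genes of the type I interferon response fell in distal regions at 7 of 24, rose at 2 (Ifitm3 and Irf7) and did not pass at 15 (the same counts adjusted over the list alone; camera adjusted p = 0.0389, median −0.16). The list's adjusted p was 0.270 with an estimated correlation, the highest of 16 alternatives whose lowest was 0.00381. Distal regions of Rsad2, which encodes the antiviral protein viperin, fell by 0.46 ± 0.09 (edgeR adjusted p = 2.55e-05) and those of Ifitm3 rose by 0.33 ± 0.06. The list's call was also lost with the replicate number as a block (0.0530), within 20 kb (0.0793), without day 7 replicate 1 (0.0546), 3 (0.0625) or 4 (0.0595), and without day 21 replicate 4 (0.0501). At gene ends 11 of 31 fell and 20 did not pass (11 adjusted over the list alone; camera adjusted p = 0.103), or 8 fell and 3 rose with trended offsets. Without day 7 replicate 2 the adjusted p at gene ends was 0.0480 and with fry 0.00386, in a range of 0.00386 to 0.517 over 17 alternatives. The gene-end median lay at percentile 1.71 of matched random lists. Oas3 (−0.68 ± 0.14) and Ifit1 (−0.69 ± 0.14), which shares a region with Ifit1bl2, fell. Isg15 had −0.33 ± 0.11 (edgeR adjusted p = 0.0185). The call was lost without day 7 replicate 4 (0.0920), without day 21 replicate 1 (0.0683) and with trended offsets (0.0624), in a range of 0.00572 to 0.0920 over 20 alternatives.

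Cytokine and chemokine genes fell at 11 of 25 gene ends, rose at 3 (Cxcl2, Il18 and Cxcl16) and did not pass at 11 (the same counts adjusted over the list alone; camera adjusted p = 0.263), or 9 and 5 with trended offsets. With fry the adjusted p was 0.00988, the lowest of 17 alternatives whose highest was 0.664. Their median lay at percentile 0.12 of matched random lists of gene ends. Il18 lost its call without day 21 replicate 3 (0.0511, the highest of 20 alternatives whose lowest was 1.40e-05). Cxcl16 lost its call without 5 libraries (up to 0.220, without day 21 replicate 3), in a range of 1.80e-04 to 0.646. Ccl5 fell from 11.5 ± 1.33 to 3.48 ± 0.730 CPM (edgeR adjusted p = 5.39e-13) and Il27 by 0.73 ± 0.10. Cxcl9, a chemokine that recruits T cells through CXCR3, had −0.25 ± 0.08 (edgeR adjusted p = 0.0156). This was lost without day 7 replicate 3 (0.128) or 4 (0.0577), without day 21 replicate 2 (0.0532) and with trended offsets (0.197), in a range of 0.00738 to 0.197 over 20 alternatives. Il12b, a subunit of interleukin 12, had 55.5 ± 0.751 and 57.9 ± 3.08 CPM (0.06 ± 0.06, edgeR adjusted p = 0.525). Its adjusted p ran from 0.0313, with trended offsets, to 0.975 over 20 alternatives. In distal regions 7 of 23 fell, 3 rose and 13 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.106; 0.0326 with fry, the lowest of 16 alternatives whose highest was 0.453). Distal Ccl22 fell by 0.90 ± 0.11 and distal Il1b rose by 0.37 ± 0.05. Genes of the NF-kB pathway fell at 10 of 28 gene ends and 18 did not pass (10 adjusted over the list alone; camera adjusted p = 0.215), or 6 fell and 3 rose with trended offsets. Fry gave 0.0355, the lowest of 17 alternatives whose highest was 0.664, while the median lay at percentile 23.7 of matched random lists. Tnip1, an inhibitor of the pathway, fell by 0.90 ± 0.15 and Map3k14, which encodes its noncanonical kinase NIK, by 0.32 ± 0.06. Distally 6 of 28 fell, 4 rose and 18 did not pass (7 and 5 adjusted over the list alone; camera adjusted p = 0.488), or 8 and 1 with trended offsets. Distal Traf2 fell by 1.11 ± 0.11 and distal Tnip1 by 0.34 ± 0.06.

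Genes of cDC1 identity gained accessibility in distal regions at 10 of 22, lost it at 2 (Tlr11 and Btla) and did not pass at 10 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0233, median 0.17). Its adjusted p was 0.453 with an estimated correlation, the highest of 16 alternatives whose lowest was 0.00287. Btla lost its call without day 7 replicate 1 (0.0804) and without day 21 replicate 2, in a range of 1.93e-04 to 0.166 over 19 alternatives. Distal regions of Clec9a, the receptor for dead cells that marks cDC1s, rose from 56.3 ± 1.80 to 80.9 ± 7.51 CPM (0.52 ± 0.06, edgeR adjusted p = 9.18e-10) and those of Cd24a by 0.46 ± 0.06. The list's call was also lost with trended offsets (0.0659), without day 7 replicate 2 (0.0691) and within 100 kb (0.0628). At gene ends 4 of 22 rose, 3 fell and 15 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.0878), or 10 and 1 with trended offsets (0.0475, in a range of 0.00464 to 0.517 over 17 alternatives). Irf8, the transcription factor on which cDC1s depend, fell from 54.8 ± 5.91 to 38.2 ± 2.84 CPM (−0.51 ± 0.07, edgeR adjusted p = 8.15e-08). Naaa rose by 0.36 ± 0.06 at ends that share a region with Ppef2 (0.13 at the end with more counts, adjusted p = 0.119, the highest of 20 alternatives whose lowest was 2.75e-09). Xcr1 (−0.08 ± 0.11), Batf3 (−0.07 ± 0.07), Zbtb46 (−0.08 ± 0.08) and Flt3 (−0.01 ± 0.07) did not pass at their ends (edgeR adjusted p from 0.470 to 0.906). Clec9a had 0.21 ± 0.10 (edgeR adjusted p = 0.102) and 0.0207 without day 7 replicate 4 (6.92e-05 to 0.437 over 20 alternatives). Markers of cDC2s rose at 2 of 16 gene ends, Il1r2 (0.37 ± 0.09) and Klf4 (0.21 ± 0.06; 0.11 at the end with more counts, adjusted p = 0.115, the highest of 20 alternatives whose lowest was 2.11e-06). They fell at 1, Clec4a4, and did not pass at 13 (the same counts adjusted over the list alone; camera adjusted p = 0.103). Distally 4 of 15 rose, 2 fell and 9 did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.960, with a median of 0.08 and a mean of −0.04), or 2 and 2 with trended offsets. Distal Sirpa fell by 0.21 ± 0.06 and Itgam rose by 0.19 ± 0.06.

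Inhibitory and tolerance genes fell at 5 of 22 gene ends (Socs1, Lilrb4a, Pdcd1lg2, Entpd1 and Axl), rose at 1 (Havcr2) and did not pass at 16 (the same counts adjusted over the list alone; camera adjusted p = 0.556), or 3 and 2 with trended offsets. Fry gave 0.00557, the lowest of 17 alternatives whose highest was 0.664, while the median lay at percentile 11.8 of matched random lists. Socs1, an inhibitor of cytokine signalling, fell by 0.31 ± 0.06 and Lilrb4a by 0.44 ± 0.12. Pdcd1lg2 lost its call without day 7 replicate 4 (0.0527, the highest of 20 alternatives whose lowest was 0.00155) and Axl without 3 libraries (up to 0.104, without day 7 replicate 2), in a range of 0.00479 to 0.148. Entpd1 lost its call with trended offsets (0.165, the highest of 20 whose lowest was 0.00413) and Havcr2 with only the end with more counts (0.0762, the highest of 20 whose lowest was 5.07e-05). Cd274, which encodes the checkpoint ligand PD-L1, had 30.4 ± 2.92 and 26.7 ± 1.78 CPM (−0.19 ± 0.08, edgeR adjusted p = 0.0676). For Cd274 the adjusted p was 0.0341 without day 7 replicate 1, 0.0406 without day 7 replicate 2 and 0.0463 without day 21 replicate 2, in a range of 0.0341 to 0.455 over 20 alternatives. Distally 4 of 23 rose, 3 fell and 16 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.567, downward, with a median of 0.00 and a mean of −0.04), or 2 and 5 with trended offsets. Distal Cd200 fell by 0.57 ± 0.06 and Pdcd1lg2, which encodes PD-L2, by 0.35 ± 0.05.

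Of the other metabolic and growth lists, none passed at an adjusted p under 0.05 by camera. With fry the lysosome (0.00667), lipid (0.00451) and cell cycle (0.0246) lists passed at gene ends and glycolysis in distal regions (0.00287), the lowest of 17 and 16 alternatives whose highest values were 0.815, 0.783, 0.664 and 0.982. Fry does not set a list against the general fall of gene ends. Among matched random lists the lysosome, lipid and cell cycle medians at gene ends lay at percentiles 58.1, 17.5 and 10.5. Glycolysis and hypoxia genes rose at 3 of 27 gene ends, fell at 8 and did not pass at 16 (4 and 8 adjusted over the list alone; camera adjusted p = 0.539, upward, with a median of −0.08 and a mean of −0.02), or 9 and 3 with trended offsets. Distally they rose at 8 of 27, fell at 1 (Kdm3a) and did not pass at 18 (8 and 2 adjusted over the list alone; adjusted p = 0.826), or 5 and 6 with trended offsets. The glucose transporter gene Slc2a1 fell by 0.29 ± 0.07 and Gapdh by 0.26 ± 0.06 at their ends, while distal regions of the oxygen sensor gene Egln1 rose by 0.64 ± 0.07 and those of Bnip3 by 0.56 ± 0.09. Lysosome and autophagy genes fell at 9 of 32 gene ends and 23 did not pass (9 adjusted over the list alone; camera adjusted p = 0.353; 3 and 3 with trended offsets). The cathepsin gene Ctsd fell by 0.56 ± 0.10 and Psap by 0.48 ± 0.10. Distally 5 of 29 rose, 4 fell and 20 did not pass (the same counts adjusted over the list alone; adjusted p = 0.960; 4 and 5 with trended offsets). Distal Uvrag rose by 0.34 ± 0.05 and distal Atp6v0e fell by 0.55 ± 0.11. Lipid and cholesterol genes rose at 2 of 26 gene ends, fell at 9 and did not pass at 15 (2 and 11 adjusted over the list alone; camera adjusted p = 0.566; 3 and 3 with trended offsets). Mylip, which marks the LDL receptor for degradation, fell by 0.86 ± 0.09 and the nuclear receptor gene Pparg rose by 0.71 ± 0.12. In distal regions 4 of 29 rose, 7 fell and 18 did not pass (the same counts adjusted over the list alone; adjusted p = 0.398, with a median of 0.01 and a mean of −0.13). Among them the fatty acid desaturase genes Scd2 (−0.51 ± 0.06) and Scd1 (−0.41 ± 0.07) fell. Cell cycle genes fell at 11 of 34 gene ends and 23 did not pass (11 adjusted over the list alone; camera adjusted p = 0.250; 2 fell and 1 rose with trended offsets), among them Top2a (−0.43 ± 0.08) and Mcm5 (−0.27 ± 0.06). Distally 6 of 26 rose, 7 fell and 13 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.882, downward, with a median of 0.02 and a mean of 0.06). Distal Tyms rose by 0.38 ± 0.08 and distal Ccne1 fell by 0.25 ± 0.05.

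Markers of other cell types that the sort could hold were measured in the same way. T and NK cell markers at gene ends rose at 2 of 16 (Klrb1c and Klrk1, receptors of NK cells), fell at 5 (Bcl11b, Gzmb, Prf1, Tcf7 and Eomes) and did not pass at 9 (the same counts adjusted over the list alone; camera adjusted p = 0.808). Fry gave the list 0.0355, the lowest of 17 alternatives whose highest was 0.971, and its median lay at percentile 0.67 of matched random lists. Eomes lost its call without day 7 replicate 3 (0.0590, the highest of 20 alternatives whose lowest was 0.00221), and Klrk1 without day 21 replicate 3 (0.0712, the highest of 20 whose lowest was 0.00175). Bcl11b had 2.13 ± 0.645 CPM at day 7 and 0.580 ± 0.524 at day 21 (−2.03 ± 0.42). Klrb1c rose by 0.51 ± 0.11, a call lost with windows of 500 bp (0.786, the highest of 20 alternatives whose lowest was 4.66e-05). Distal regions of Tcf7 fell from 21.8 ± 3.52 to 8.36 ± 1.24 CPM (−1.40 ± 0.12) and those of Cd247, a T cell receptor signalling chain, by 2.17 ± 0.24. Melanoma markers, which would come from tumour cells, rose at 1 of 11 gene ends (Mitf), fell at 4 (Tyrp1, Slc24a5, Sox10 and S100b) and did not pass at 6 (the same counts adjusted over the list alone; camera adjusted p = 0.808). The Mitf call was lost without 5 libraries (up to 0.0828, without day 21 replicate 3), in a range of 2.22e-04 to 0.0828 over 20 alternatives. For Sox10 it was lost without day 7 replicate 3 or day 21 replicate 4 (0.174, the highest of 19 whose lowest was 0.00638). For S100b it was lost without day 7 replicate 2 or 3 and with the replicate number as a block, in a range of 0.0242 to 0.205 over the 15 alternatives that tested it. Tyrp1 fell from 1.32 ± 0.546 to 0.301 ± 0.273 CPM (−2.23 ± 0.53). Slc24a5 fell to 0.373 ± 0.175 CPM (edgeR adjusted p = 0.00973), which was lost without day 21 replicate 4 (0.0553, in a range of 0.00697 to 0.0553 over 18 alternatives). Distal melanoma regions rose at Trpm1 (0.14 ± 0.05), fell at Tyrp1 (−2.03 ± 0.52) and did not pass at 10 of 12 (0 and 1 adjusted over the list alone; camera adjusted p = 0.333; 0 and 3 with trended offsets). The Trpm1 call was lost without any day 7 library (0.0607 to 0.146) and without day 21 replicate 2 (0.126) or 3 (0.168), in a range of 3.36e-04 to 0.241 over 19 alternatives. It was also lost with RLE size factors (0.0605), DESeq2 (0.0516), limma-voom (0.0546), trended offsets (0.241) and thinning (0.0764). Stromal and endothelial markers rose at 1 of 9 gene ends (Vwf), fell at 2 and did not pass at 6 (the same counts adjusted over the list alone; camera adjusted p = 0.808). The Vwf call (edgeR adjusted p = 0.0410) was lost in 11 of 19 alternatives, among them DESeq2, limma-voom, thinning and the omission of any of 7 libraries (up to 0.137, without day 7 replicate 2), in a range of 0.00224 to 0.137. The fibronectin gene Fn1 fell by 0.99 ± 0.23 and Cdh5 by 1.02 ± 0.32. Distally the stromal markers fell at 3 of 14 (Acta2, Sparc and Cdh5) and did not pass at 11 (3 adjusted over the list alone; camera adjusted p = 0.0734). Without day 21 replicate 2 this adjusted p was 0.0480, with trended offsets 0.0442 and with fry 0.0399, in a range of 0.0399 to 0.356 over 16 alternatives. Distal Cdh5 lost its call without day 7 replicate 2 (0.0669, the highest of 19 alternatives whose lowest was 0.00158).

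Macrophage and monocyte markers rose at C1qc, C1qa, Ly6c2 (0.38 ± 0.10), Cd68 and Cd14 and fell at Cx3cr1 among 21 gene ends (5 and 1 adjusted over the list alone; 5 and 0 with trended offsets). Leaving out 1 library ended the calls of C1qa (up to 0.126, without day 7 replicate 3; 0.00327 to 0.126 over 20 alternatives) and Cd14 (0.0708, without day 21 replicate 4; 7.59e-04 to 0.120). It also ended those of Cx3cr1 (up to 0.129, without day 7 replicate 3, and 0.00523 to 0.207 over 20 alternatives) and Cd68 (up to 0.0963, without day 21 replicate 3, and 1.81e-05 to 0.537). Without day 7 replicate 3 the list had an adjusted p of 0.0345, in a range of 0.0345 to 0.517 over 17 alternatives. In distal regions 4 of 20 rose, 4 fell and 12 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.826, downward, with a median of 0.02 and a mean of 0.03; 2 and 4 with trended offsets). Distal Csf1r rose by 0.22 ± 0.06 and distal Cebpb fell by 0.25 ± 0.07. The Cebpb fall was −0.16 within 20 kb (0.121) and −0.02 within 100 kb (0.762), and its adjusted p ran from 9.81e-04 to 0.762 over 19 alternatives. Neutrophil markers did not pass at any of 9 gene ends (edgeR called 0, with 0 at an unadjusted p under 0.05; camera adjusted p = 0.215), and DESeq2 and limma-voom also called 0. Distally they rose at 2 of 12, Retnlg (0.34 ± 0.07) and Mmp9 (0.19 ± 0.07), with 10 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.960, downward, with a median of 0.01 and a mean of 0.00). Distal Mmp9 lost its call without day 7 replicate 1 (0.0899) or 2 (0.0531) and without day 21 replicate 2 (0.112) or 3 (0.0816), in a range of 0.0284 to 0.112 over 19 alternatives. B cell markers rose at Fcrla (0.60 ± 0.09) alone among 11 gene ends (1 adjusted over the list alone; camera adjusted p = 0.404, upward, with a median of −0.05 and a mean of −0.02). In distal regions 2 of 11 rose (Fcrla, 0.22 ± 0.07, and Pax5), Blnk fell by 0.36 ± 0.08 and 8 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.830; 1 and 1 with trended offsets). Distal Pax5 lost its call without 5 libraries (up to 0.190, without day 21 replicate 3), in a range of 0.00354 to 0.734 over 19 alternatives. Distal Fcrla lost its call without day 7 replicate 4 (0.151) or day 21 replicate 4 (0.0900), in a range of 0.00652 to 0.151 over 19 alternatives. Markers of plasmacytoid dendritic cells rose at 2 of 7 gene ends (Plac8 and Siglech), fell at 2 (Lag3 and Tcf4) and did not pass at 3 (the same counts adjusted over the list alone; camera adjusted p = 0.216; 3 and 1 with trended offsets). Siglech lost its call without 7 libraries (up to 0.149, without day 21 replicate 1), in a range of 0.0255 to 0.178 over 20 alternatives. Plac8 rose from 28.2 ± 3.10 to 45.5 ± 3.79 CPM (0.70 ± 0.08), and Lag3, an inhibitory receptor gene whose ends share a region with Ptms, fell by 0.25 ± 0.07. Distally 3 of 13 rose, 2 fell and 8 did not pass (the same counts adjusted over the list alone; camera adjusted p = 0.720). Distal Plac8 rose by 0.48 ± 0.05 and distal Runx2 fell by 0.60 ± 0.09, which within 20 kb was −0.01 (0.987, the highest of 19 alternatives whose lowest was 3.00e-08).

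Between libraries, Pearson correlations of log2 CPM across regions were 0.926 to 0.951 within day 7, 0.947 to 0.966 within day 21 and 0.891 to 0.929 between the days. Totals did not separate the days (exact permutation p = 0.0571, 0.0816 adjusted over 10 library measures). The share of counts on chromosome X was 1.79% ± 0.0137 and 1.78% ± 0.0384 (exact permutation p = 0.514, adjusted 0.571), and that on chromosome Y was 0.00588% ± 0.000281 and 0.00494% ± 0.00121 (exact permutation p = 0.114, adjusted 0.143). Counts on unplaced contigs made up 0.124% ± 0.0167 and 0.0874% ± 0.0101 (exact permutation p = 0.0286, adjusted 0.0571).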

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

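Both comparisons of losses between maturation and T cell genes, the test of library depth on mitochondrial genes and the test of library depth on immediate-early genes were chosen only after the results were seen; the other tests here were set down before they were run. Of 274 groups of 4 libraries, 16 had a library far from the other 3, where chance gives about 1 in 20 groups, or 13.7.

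The number of changed features was set against all 35 splits of the 8 libraries into 4 and 4. Only the real split, 1 of 35, gave as many changed regions (23590), genes changed at their ends (4250) and genes changed in distal regions (4308). This is the smallest share that 35 splits can give. The other splits mix the days, so a difference between the days widens the spread within their groups. The comparison therefore cannot exclude chance assignment, nor tell the day from anything else that varied with it. In edgeR the other splits gave at most 0 of each at an adjusted p under 0.05, and at most 11774, 2174 and 1599 at an unadjusted p under 0.05 against 37725, 5610 and 5697 in the real split.

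Of 29 dendritic cell maturation genes, 16 were lower at day 21 at their ends, 1 was higher and 12 did not pass. As a bound, fewer contaminating T cells were taken to remove at most the signal that T cells had at their own genes. This assumes that T cells are no more accessible at maturation genes than at their own, which was not tested. The median loss of the 16 genes was 8.70 CPM, 1.57 times the median day 7 level of the 7 T cell core genes with a region (5.56 CPM, exact permutation p = 0.512), so this bound was not exceeded beyond its spread. The loss was 4.18 times the median loss of these T cell genes (2.08 CPM, exact permutation p = 9.79e-04), but the 16 genes were chosen because they fell, so this comparison decides nothing. Over all 29 measured genes of the list the median loss was 4.44 CPM, 2.36 CPM more than that of the T cell genes (exact permutation p = 0.210, in which genes are not independent replicates). A loss of T cells therefore stays open, and distal T and NK cell markers did fall. After thinning every library to the smallest total 15 of the 16 genes remained called, so unequal counts alone do not account for most of these calls. Thinning keeps each gene's expected share of counts, so it cannot address other differences between libraries that go with depth. A smaller share of CCR7-expressing mature cells among the sorted cDC1s stays open and was not tested.

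Of 74 gene ends each, 31 of oxidative phosphorylation and 30 of the mitochondrial ribosome were lower at day 21, while 43 and 42 did not pass and 2 of the ribosome rose. The broad drop at gene ends was argued against by random lists matched on abundance, among which the medians of oxidative phosphorylation and of the mitochondrial ribosome lay at or below percentile 0.06. Unequal counts were argued against by thinning, for oxidative phosphorylation alone. Its median lay below that of all gene ends by −0.0622 after and −0.0873 before, at percentile 1.54 of matched lists. The mitochondrial ribosome median was not placed in this way. Other differences that go with depth were not addressed, since thinning keeps each gene's expected share of counts. A bias linked to GC content, common at promoters of such genes, could not be examined without sequence and stays open, as does joint movement of the genes, since an estimated correlation gave an adjusted p of 0.517. A change with tumour stage may be a further explanation and was not tested apart from these.

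Immediate-early genes split at gene ends, with 9 list members higher at day 21 and 8 lower. Of the 9, 8 remained called higher after thinning, so unequal counts alone do not account for most of these 9 calls. Other differences that go with depth stay open, since thinning keeps each gene's expected share of counts. The list stayed split after thinning, with 8 higher and 9 lower and a median of −0.01. A stress response to tissue handling or in the tumour cannot be told apart from the day. Heat-shock chaperone genes, which such stress could raise, had a median of −0.0178 over 12 gene ends and 0.330 over 9 genes in distal regions, with 3 called higher and 3 lower, and handling was confounded with the day.

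On chromosome Y, day 21 replicate 1 had 0.00313% of counts against 0.00533% to 0.00568% in the other 3 libraries (gap over range 0.863). On chromosome X, day 7 replicate 2 had 1.81% against 1.79% in the others (0.845). H2-K1 ends were lowest in day 21 replicate 1, at 53.8 CPM against 59.1 to 59.6 (0.924), and so were Lag3 ends, at 49.6 against 63.3 to 64.2 CPM (0.941). In day 7 replicate 2 the region near Slco5a1 had 24.1 CPM against 20.8 to 20.9 (0.947), Zbtb46 ends 36.01 against 32.7 to 32.8 CPM (0.962), Opa1 ends 28.7 against 26.03 to 26.48 CPM (0.833) and Mrps18b ends 139.5 against 121 to 123 CPM (0.932). In day 7 replicate 3 the region near Ccr7 had 21.8 CPM against 15.97 to 16.78 (0.860) and B2m ends 83.4 against 69.0 to 71.2 CPM (0.850). In day 21 replicate 4 B2m ends had 59.6 against 56.0 to 56.5 CPM (0.856) and Gapdh ends 51.6 against 56.6 to 57.3 CPM (0.882). Oas3 ends in day 21 replicate 2 had 8.78 against 6.66 to 6.96 CPM (0.858), and distal Uvrag regions in day 21 replicate 3 had 217 against 179 to 185 CPM (0.839). The remaining groups of the 16 had gaps over range of 0.920 and 0.843, and what they measure is not reported here.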

How the results depend on the processing

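Thinning to the smallest library and the gene end with more counts were chosen only after the data were seen, as was the use of other windows and distances for the list tests; all other alternatives were planned. The counts of changed regions (23590), gene ends (4250) and distal sums (4308) stayed within 1.5 times under every alternative run except a test against a 1.5-fold change, which left 3113, 57 and 162 by its construction. With DESeq2 they were 21536, 3981 and 4069, with limma-voom 23814, 4282 and 4308, and after thinning 18957, 3859 and 3755. No feature called in both turned direction when scaling, filter, test, block or libraries were changed. With windows of 500 and 2000 bp 4 and 4 gene ends did, with only the end with more counts 1, and within 20 and 100 kb 9 and 3 distal sums. Leaving out 1 library at a time gave 18691 to 23106 regions, 3320 to 4451 gene ends and 3582 to 4286 distal sums, 4 to 6 lists at gene ends and 4 to 6 in distal regions, a difference (day 21 minus day 7) in the gene-end share of −2.489 to −1.9998 points, on chromosome X of −0.0320 to −0.00304 points, on chromosome Y of −0.00119 to −0.000339 points, and in totals (in units of the CPM denominator) of 3.70 to 8.28.

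Camera called 5 lists at gene ends and 5 in distal regions; with an estimated correlation 0 and 0 were called, and with fry, which asks another question, 14 and 10. Windows of 500 bp gave 9 lists at gene ends; the cause was not tested. Counting each list once per alternative, 743 results kept their side of the threshold, 27 gained and 22 lost a call. Of 133 named genes and regions, 41 kept their side of the threshold in every alternative; counting each item once per alternative, 2542 results kept it, 9 gained and 130 lost a call, 87 of these in the test against a 1.5-fold change, and none reversed. Of 243 list members called at gene ends 124 kept their call in every alternative that tested them, 118 lost it in at least 1 (85 on leaving out a library) and 2 reversed, Cacnb3 with windows of 2000 bp and Il4i1 with only the end with more counts. Of 210 in distal regions 125 kept it, 85 lost it (70 on leaving out a library) and 0 reversed. Distal calls of Irf1, Blnk, Cebpb and Runx2 were lost within 20 kb and that of Cebpb within 100 kb, and distal Fcrla, Mmp9 and Trpm1, Naaa, H2-Ab1, Klf4 and Klrb1c at their ends, Cdh5 with windows of 2000 bp and Lag3 with trended offsets also lost theirs in at least 1 alternative. With the replicate number as a block there were 23276 regions, 4604 gene ends and 4470 distal sums, and beyond the distal interferon list (0.0530) the block changed no list call and no call of a gene chosen by the rule. Among list members given as examples it ended the calls of Cacnb3 (0.0529), S100b (0.0584) and Siglech (0.0507) at their ends. Deviations of libraries with the same number correlated at 0.00411 to 0.00975, and not every library correlated best with its own number, so the numbers were not treated as pairs. Offsets for GC content, alone or with the block, and both motif analyses were not run. In the simulation 17.9% of 1.5-fold changes at single regions were recovered. It changed 200 features, far fewer than the 23590 regions called in the data, which makes the adjusted threshold stricter. This share therefore does not measure how many small changes were missed here.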

Other observations

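The counts per locus here were chosen only after the data were seen. Changed regions clustered by gene: among 171 genes with at least 8 changed regions assigned to them, 54 had all of these in 1 direction, 33 higher and 21 lower, where 1000 permutations of the directions gave a median of 1 and at most 4. Loci that lost accessibility included Il2ra, the alpha chain of the interleukin 2 receptor (11 regions of 17 tested), Stat4, a transcription factor of interleukin 12 signalling (11 of 22), Bhlhe40 (10 of 20), Pdcd1lg2 (10 of 27), Irf1 (9 of 21), Ccr7 (9 of 16) and Egr2 (8 of 10). Loci that gained it included Gng2 (13 of 28), the kinase gene Lrrk2 (12 of 20), Plet1 (12 of 23), Ezr, which encodes the membrane linker ezrin (11 of 20), Ifngr1, the interferon gamma receptor chain (10 of 22), Inpp5d (10 of 20), Dusp1 (9 of 15) and Tm6sf1 (8 of 9). Neighbouring changed regions had the same direction in 65.7% of pairs, against 50.0% expected. Permuting directions treats regions as independent, which neighbours are not.

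Of 12 heat-shock chaperone genes 3 fell at their ends, 0 rose and 9 did not pass, and 5 of the 12 had positive changes. Hsp90ab1 (−0.22 ± 0.06), Hspe1 (−0.17 ± 0.06) and Hspd1 (−0.17 ± 0.06) fell there, while distal regions of Hsp90aa1 (0.33 ± 0.06), Dnajb1 (0.35 ± 0.12) and Hspb1 (2.29 ± 0.52) rose, and Hspa1a had 63.0 ± 5.40 CPM at day 7 and 66.3 ± 20.2 CPM at day 21.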
